A study of Mus musculus with 6 samples.

How the data were processed

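RNA from cells sorted out of mice that carry a GFP reporter under the smooth muscle actin (Acta2) promoter was measured on 6 1-colour Agilent arrays. Per the labels and the series' design text, the cells were negative for CD45, a marker of white blood cells, and CD31, a marker of endothelial cells. Cells with low GFP came from the dermis and are called skin cells here. Cells with high GFP came from wounds 7 days after injury and are called wound cells. Each group has 3 arrays. Replicates 1 and 2 of each group were on array design 026655 and 1 array of each group was on design 028005. The labels give the last arrays no number, and they are called replicate 3 only as a name. Per the series' design text, RNA was taken up in TRIzol, checked by capillary electrophoresis and amplified from about 50 ng with a low-input labelling kit. The design text names a human 8x60K array beside a whole-genome array, while the organism label of all 6 samples is mouse. The probes of both designs were named here as mouse genes.

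Per the file headers, the authors extracted the spot intensities of each array with Agilent Feature Extraction 10.7.3.1, and the design files name genome build mm9. The deposited scanner files hold linear intensity values, not scaled between arrays, and the processed signal used here is the software's background-subtracted and detrended value. The authors' table holds gene values merged over both designs with GeneSpring 14.5, per the series' design text. Neither the labels nor the table state its scale. The authors' table values were set against the scanner values of each skin and wound pair, and differences between arrays matched log2 differences with slopes of 1.00, 1.00 and 0.984 and Pearson correlations of 0.99996, 0.99996 and 0.979 over 16564 genes, so the scale was taken as log2 with the same direction. The 75th percentile of each of its columns is 0. The column medians are -0.21, -0.25 and -0.25 for skin replicates 1, 2 and 3 and -0.28, -0.27 and -0.23 for wound replicates 1, 2 and 3. How the probes of a gene were combined for that table is not given in the sources used here. The scanner values set against it were means of all probes of a gene, and it matched them closely in replicates 1 and 2. The mean of all probes and the authors' deposited table, often given side by side below, are thus not independent alternatives. All of its columns of sample values were matched to samples.

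The scanner files carry no column of gene names, so the planned use of the file's names was replaced. Probes were named through the gene identifiers that the authors' table pairs with probes, and otherwise through the RefSeq accession of the probe, without version, in a table of gene names for assembly GRCm38.p6 that was used for names only. On design 026655, 30633 of 39429 probes received a symbol, 26442 by the authors' table and 4191 by accession. On design 028005, 30659 of 55681 probes did, 26442 and 4217 by the same sources. On each design 1319 probes had an identifier without a current symbol, and 7477 and 23703 probes stayed unnamed. Where both sources named a probe they gave the same gene for 23282 of 23323 probes on design 026655 and for 23430 of 23445 on design 028005. Of 19267 gene identifiers in the authors' table, 18040 were found in the name table.

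Control spots and spots with an outlier mark were left out, and spots of one probe were averaged. The values tested were the log2 of the processed signal minus the array's 75th percentile. For each gene and design the probe with the highest mean was used, which was the same probe on both designs for 97.6% of genes. Of 22912 genes on both designs, 16713 had a probe well above background on all 3 arrays of at least 1 group and were tested, 879 of them known by an identifier without a symbol. The test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) of wound against skin with the array design as a fixed term, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Each standard error (SE) comes from this model on 3 arrays per group, with 3 residual degrees of freedom and 6.23 after the variances were moderated. Each array design was 1 slide and 1 scan with both groups on it, so the term for the design also covers slide and scan. Values within each design are given beside the pooled ones. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

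A probe that was well above background on no array of a group has only a bound there. It is written as at least N-fold, which sets the mean of the bright group against the mean, per array, of the higher of the probe's own signal and the lowest signal of any probe well above background. Its adjusted p is that of the model. The bound is that of the probe and of the processed signal, and does not hold on a scale with an added offset or for a gene whose other probes were detected. Where some arrays of a group measured the probe, their number is given. Of genes with several detected probes, 4711 in all, 1931 had a called probe and 15 had probes called in both directions. None of those 15 is named.

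Before the data were examined, 37 gene lists with 1209 entries, the tests, the alternatives and a rule for the genes to be named were fixed. Of the entries, 1204 have a current symbol, 27 of them updated from an older one. Counts of members below are of those that entered the gene test, which for some lists of other cell types were far fewer than the entries. The rule names Acta2, Ptprc and Pecam1, the 12 called genes with the largest increase and the 12 with the largest decrease that had the same sign in all 3 pairs of arrays, and the 3 called members of each list with the largest change. Genes outside the rule were chosen after their values were seen, which is said where they are first named or at the head of the part. Some members of the lists are counted but not reported by name here. Each list was tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 37 lists, and again with a correlation estimated from the arrays. The fry test, which asks whether a list differs from no change and not from other genes, was run beside them. With an estimated correlation camera rests on the 3 residual degrees of freedom of the model. It then has little power over 37 lists, and a missing call is weak evidence.

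The alternatives tried were no array design term, the pair of arrays as a block, the 4 arrays of design 026655 alone, quantile normalization, the 75th percentile over detected probes, normexp background correction with an offset of 50, the mean of all probes, probes on both designs only, no filter, detection on all 6 arrays, eBayes with trend and robust, the authors' deposited table, an adjusted p under 0.01, and leaving out each array in turn. With the design term, leaving out either array of design 028005 is the same fit as the 4 arrays of design 026655 alone. Normexp was run on the median signal because the files hold no mean signal column. The model was tested on simulated data for the wound against skin comparison with 16713 genes, of which 200 were changed in 4 sizes of 50 genes. It called 0% of genes changed by a log2 of 0.5, 6% at 1, 62% at 2 and 88% at 3, with 5 false calls. The simulated genes varied independently of each other. Of 20 unchanged lists 0 passed an unadjusted p of 0.05, and a shifted list was called. Only 200 of 16713 genes were changed in the simulation, while 34.0% were called in the data. The Benjamini-Hochberg threshold depends on that share, so the rates for genes do not give the power of the real comparison. In the data 5676 genes were called, and 3371 of them differed 2-fold or more.

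Probes with neither a symbol nor a gene identifier were kept out of the gene test and are described apart. No outlier test was run because the groups hold 3 arrays. No gene annotation of build mm9 was used here.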

Results

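Gene expression was compared between 2 sorted populations of mouse stromal cells, skin cells with a low signal of the smooth muscle actin reporter and wound cells with a high signal 7 days after injury. The labels call the skin cells fibroblast-like and the wound cells myofibroblasts, the contractile cells of healing tissue. Each population was measured on 3 arrays. The share of spots well above background was 70.1%, 65.2% and 72.6% on skin replicates 1, 2 and 3 and 71.1%, 65.3% and 64.4% on wound replicates 1, 2 and 3. No array had saturated spots (0 on each). Spots with an outlier mark, which were left out, numbered 147, 138 and 249 on skin replicates 1, 2 and 3 and 89, 117 and 678 on wound replicates 1, 2 and 3. Correlations between arrays of a group lay between 0.969 and 0.989 across genes, and those between arrays of different groups between 0.901 and 0.923. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

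The comparison asks which genes set the high-reporter cells of wounds apart from the low-reporter cells of uninjured dermis. Reporter level and injury go together here, since no high-reporter skin cells and no low-reporter wound cells were measured. A difference can belong to either, and they cannot be told apart. Acta2, the smooth muscle actin gene whose promoter drives the reporter, was 26.1-fold higher in wound cells (log2 4.71, SE 0.16, adjusted p = 5.41e-05). It checks the labels and is no independent finding, since the reporter set the sort. The difference was 4.99, 4.47 and 4.66 in replicates 1, 2 and 3. Wound cells had far more RNA of the matrix metalloproteinases Mmp10 and Mmp9, of the imprinted genes H19 and Dlk1, of the growth factor Ptn and of the secreted collagen triple helix protein Cthrc1. Skin cells had far more of Cyp2f2, a cytochrome P450 enzyme, of Bmp4, a bone morphogenetic protein, of the scavenging chemokine receptor Ackr4 and of Coch, an extracellular matrix protein. In all, 5676 of 16713 genes (34.0%) differed, 3086 higher and 2590 lower in wound cells, and each of the 5676 had the same sign in the 3 pairs of arrays. The calls were made from these same differences, so the shared sign is no separate support. A 2-fold difference or more was reached by 1707 of the higher and 1664 of the lower genes, and an 8-fold difference by 289 and 345. The count of calls fell to 1742 with no term for the array design, a model that gave every gene the same SE of 0.62 and so called only differences of 1.74 or more on the log2 scale. It fell to 3179 at an adjusted p under 0.01 and to 3740 without skin replicate 1. Of calls at 2-fold or more, 3371 in all, normexp background correction gave 2159.

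Among the 12 genes with the largest increase, Mmp10 was at least 217-fold higher in wound cells (adjusted p = 6.76e-05) and Mmp9 at least 59.2-fold (adjusted p = 5.41e-05), because their probes were not well above background on the skin arrays. These bounds hold for the processed signal. Normexp adds an offset of 50 to each signal, which draws dim signals together, and gave a log2 of 5.18 for Mmp10 and 3.53 for Mmp9. It put all 20 named genes with a bound under that bound. The brightest probe of Brinp3 was not well above background on the skin arrays either, but a second probe was detected on all 3, and the log2 difference of the gene was 5.95 with the mean of all probes, 5.10 under normexp and 4.87 in the authors' deposited table. H19, a long noncoding RNA, rose 212-fold (log2 7.73, SE 0.48, adjusted p = 0.000148), with a log2 of 4.82 by the mean of all probes and 4.77 in the authors' deposited table. Dlk1, a transmembrane protein with EGF-like repeats, rose 186-fold (log2 7.54, SE 0.36, adjusted p = 8.74e-05). Ptn and Cthrc1 rose 128-fold and 117-fold (log2 7.00 and 6.86, SE 0.51 and 0.28), or by 7.79 for Ptn on design 026655 alone and 6.23 for Cthrc1 under normexp. The neutrophil-attracting chemokine Cxcl3, Glipr1, Prss35, the metalloproteinase Adamts16 and the homeobox gene Dbx2 were measured on 1 of the 3 skin arrays each, with log2 differences of 7.51, 7.51, 7.47, 7.15 and 6.92, or 3.91, 4.91, 4.93, 3.66 and 3.98 under normexp. On design 026655 alone Cxcl3 and Adamts16 stood at 8.10 and 7.76, and the mean of all probes gave 5.49 for Adamts16.

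Among the 12 genes with the largest decrease, Cyp2f2 was 317-fold lower in wound cells (log2 -8.31, SE 0.28, adjusted p = 5.41e-05). Ackr4 was 145-fold lower (log2 -7.18, SE 0.23, adjusted p = 5.41e-05) and Bmp4 104-fold lower (log2 -6.70, SE 0.39, adjusted p = 0.000125). Under normexp the log2 difference was -5.77 for Ackr4 and -6.05 for Bmp4, and that of Bmp4 was -3.27 with the mean of all probes, -4.35 in the authors' deposited table and -7.31 on design 026655 alone. Coch was measured on 1 of 3 wound arrays and had a log2 difference of -9.27 (SE 0.96, adjusted p = 0.000829). The same number of wound arrays measured the secreted phospholipase Pla2g5 (log2 -8.98), the organic anion transporter Slco2b1 (log2 -8.83), the serine protease inhibitor Serpina3c (log2 -8.33), the G protein-coupled receptor Gpr1 (log2 -7.97) and Ppp2r2c, a regulatory subunit of a protein phosphatase (log2 -7.63). Gldn, an adhesion protein of the node of Ranvier, was measured on 2 wound arrays (log2 -7.30). Gpm6a, a neuronal membrane glycoprotein, was at least 61.6-fold lower and the calmodulin-like gene Calm4 at least 46.1-fold lower, with adjusted p = 5.41e-05 and 0.00162. These bounds are for the mean over arrays. In the pair on design 028005 the log2 difference of Calm4 as read was -4.85, which is less than its bound. Normexp gave -3.93 for Gpm6a, -3.47 for Calm4, -7.04 for Coch, -5.74 for Pla2g5, -6.53 for Slco2b1, -5.28 for Serpina3c, -5.63 for Gpr1, -4.95 for Ppp2r2c and -5.51 for Gldn. The mean of all probes gave -6.24 for Pla2g5. On design 026655 alone Coch stood at -10.94, Slco2b1 at -9.52 and Gldn at -8.32. Gpr1 was -9.19 without wound replicate 1 and -6.85 without wound replicate 2.

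**Figure D1:**
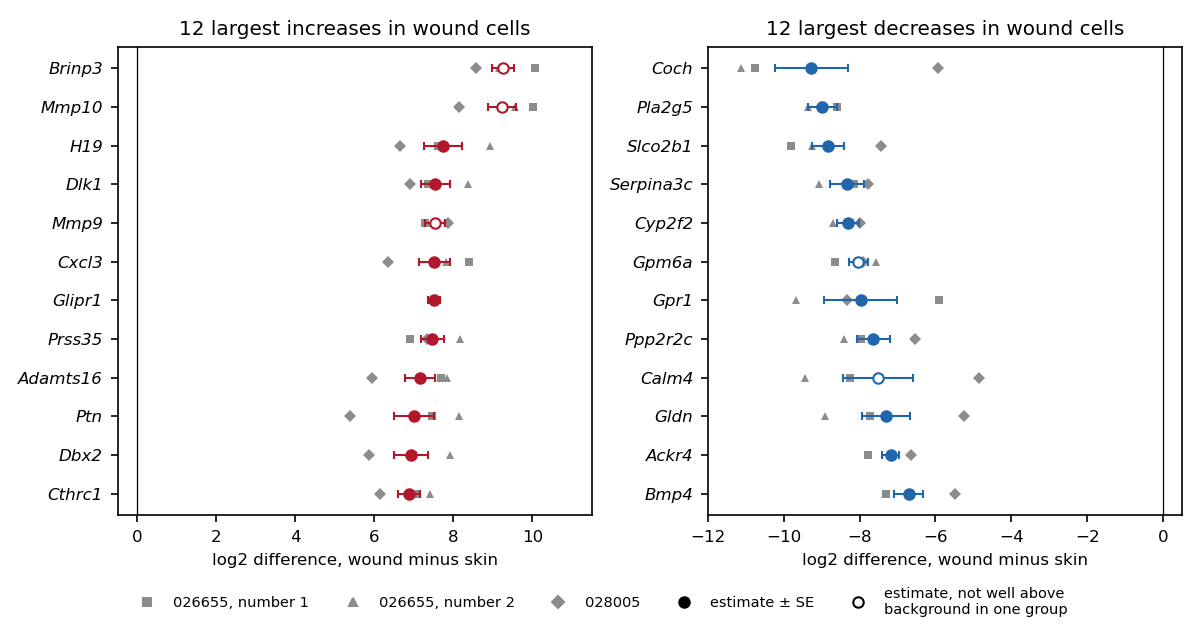
Log2 fold change of wound over skin cells for the 12 genes with the largest increase and the 12 with the largest decrease, with grey points for the 3 pairs of arrays, a coloured point with its SE for the model, and open circles where the probe used was not well above background on any array of 1 group, so that the position is no measured size. Each pair lies on the same side of 0 as the estimate, which the rule for naming these genes required. Of genes measured on all 6 arrays the increases reach 7.73 for H19 and the decreases -8.31 for Cyp2f2.

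Genes of stress fibres and contraction rose almost throughout, with 28 of 32 measured members higher in wound cells, 0 lower and 4 not past the threshold (31 and 0 adjusted over the list alone). Besides Acta2 these included the focal adhesion protein Tes (log2 5.16, SE 0.21, with 2.85 by the mean of all probes and 2.79 in the authors' deposited table), the actin-binding calponin Cnn1 (log2 4.64, SE 0.22) and Tagln, also called SM22 (log2 3.21, SE 0.14), the last chosen after its value was seen. The median change was 1.51 on the log2 scale, with 1.56 on design 026655 and 1.56 on 028005. Camera gave an adjusted p = 5.14e-13 for this list against all other genes, and an adjusted p = 0.244 with an estimated correlation. Acta2 is a member of the list. Sorting on its promoter may by itself select genes expressed with Acta2, which could include mural cell markers, and this was not tested. Markers of mural cells, the pericytes and smooth muscle of vessels, rose in the same arrays, with 25 of 32 members higher (25 adjusted over the list alone), 2 lower and 5 not past the threshold. Their median was 2.98 (2.82 on design 026655 and 2.66 on 028005), or 2.68 with 3 members at their bounds (camera adjusted p = 1.26e-10, and adjusted p = 0.244 with an estimated correlation). Higd1b, a pericyte marker, rose 33.2-fold (log2 5.05, SE 0.14), and Kcnmb1, a potassium channel subunit of smooth muscle, and Casq2, a calcium-binding protein of muscle, were at least 12.7-fold and at least 21.7-fold higher (adjusted p = 6.76e-05 and 0.000122). Rgs5, Notch3 and Myh11, chosen after their values were seen, rose 27.5-fold, 11.0-fold and 12.1-fold. The 2 members that fell, named after their values were seen, were Itga8 and Ndufa4l2, and Ndufa4l2 lost its call on design 026655 alone (adjusted p = 0.0519). The pericyte receptors Pdgfrb and Cspg4, also chosen afterwards, did not pass the threshold (log2 0.25 and -0.17, adjusted p = 0.266 and 0.474).

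Fibrillar collagen chains were split. Of 11 chains, 7 rose, 0 fell and 4 did not pass the threshold (7 and 0 adjusted over the list alone), led by Col5a3 (16.3-fold, log2 4.03, SE 0.14), Col27a1 (log2 2.35, SE 0.22) and Col24a1 (log2 2.32, SE 0.20). The chains of the main dermal collagens, chosen after their values were seen, did not pass the threshold, with a log2 difference of 0.09 for Col1a1 (SE 0.15, adjusted p = 0.675), 0.02 for Col1a2 (SE 0.16, adjusted p = 0.925) and 0.07 for Col3a1 (SE 0.17, adjusted p = 0.786). With the 75th percentile taken over detected probes the values of Col1a2 and Col3a1 were -0.05 and -0.00, and the authors' deposited table gave -0.04 for Col1a2. These chains are among the brightest genes on the arrays. Of 163 genes at least as bright as Col1a1, the dimmest of them, 14.1% were called against 34.0% of all tested genes. The list had a median of 1.13 (1.18 on design 026655 and 1.03 on 028005), an adjusted p = 0.00449 by camera and an adjusted p = 0.401 with an estimated correlation. Other collagens had 16 of 29 members higher, 4 lower and 9 not past the threshold (18 and 4 adjusted over the list alone). Col8a1 and Col12a1 rose 23.7-fold and 17.0-fold, and Col6a5 rose by a log2 of 3.34. The 4 that fell, named after their values were seen, were Col13a1, which was not well above background on the wound arrays, Col17a1, measured on 2 of 3 wound arrays, Col23a1 and Col4a4. The list's median was 1.00 (0.94 and 1.13 on designs 026655 and 028005), with a camera adjusted p = 0.00177 and an adjusted p = 0.344 with an estimated correlation.

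**Figure D2:**
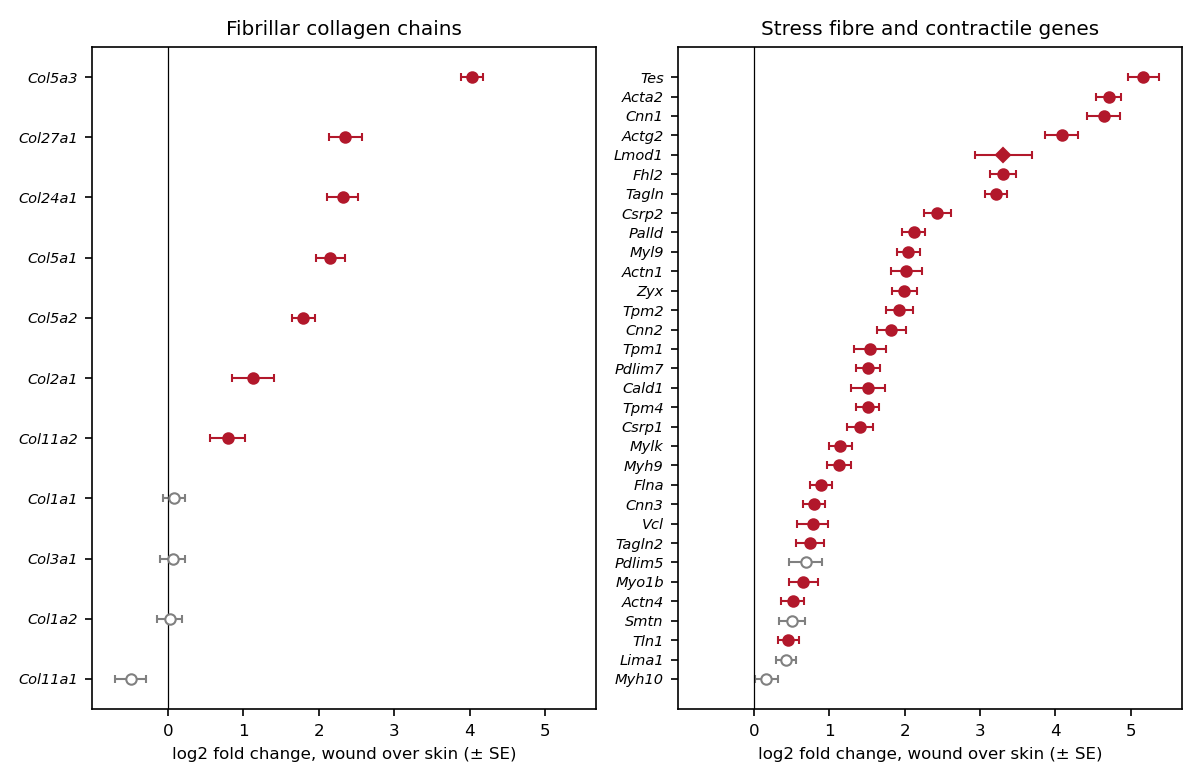
Log2 fold change of wound over skin cells with its SE for fibrillar collagen chains and for stress fibre and contractile genes, filled red where the adjusted p passed 0.05 and open grey where not, with diamonds where the probe was not well above background in 1 group. Stress fibre genes reach 5.16 for Tes, which is 2.85 with the mean of all probes, and Col5a3 reaches 4.03, while Col1a1, Col1a2 and Col3a1 lie at 0.09, 0.02 and 0.07, those of Col1a2 and Col3a1 turning to -0.05 and -0.00 with the 75th percentile taken over detected probes.

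Genes that process and crosslink collagen rose for 21 of 30 members, with 3 lower and 6 not past the threshold (23 and 4 adjusted over the list alone). The lysyl oxidase relative Loxl3 rose (log2 3.27, SE 0.23), while Loxl4 (log2 -3.51, SE 0.21), Pcolce2, an enhancer of procollagen processing (91.3-fold lower, log2 -6.51, SE 0.24), fell. The last of the 3 lower members, the protease Tll1, named after its value was seen, was measured by a different probe on each design (log2 -0.88) and did not pass the threshold with the brightest probe on both (log2 -0.13, adjusted p = 0.785). The median was 0.94 (0.98 on design 026655 and 0.89 on 028005), with a camera adjusted p = 9.11e-05 and an adjusted p = 0.344 with an estimated correlation. Matricellular and provisional matrix genes rose for 20 of 31 members and fell for 6, with 5 not past the threshold (21 and 6 adjusted over the list alone). Cthrc1 led this list, and tenascin C (Tnc) rose 18.8-fold (log2 4.24, SE 0.41). Smoc1, measured on 2 of 3 wound arrays, fell (log2 -5.81, SE 0.53). Periostin (Postn, log2 2.27), fibronectin (Fn1, log2 1.32) and Thbs4 (log2 3.19), chosen after their values were seen, rose, Fn1 losing its call with no array design term (adjusted p = 0.222). Sparc, an abundant collagen-binding protein also chosen afterwards, did not pass the threshold (log2 0.02, adjusted p = 0.947) and stood at -0.05 with the 75th percentile over detected probes. The list's median was 1.03 (1.21 and 1.18 on designs 026655 and 028005), with a camera adjusted p = 0.00231 and an adjusted p = 0.344 with an estimated correlation.

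Matrix proteases and their inhibitors rose for 26 of 45 members, fell for 9 and did not pass the threshold for 10 (26 and 11 adjusted over the list alone). Mmp10, Mmp9 and Adamts16 led the increases, and Timp1, an inhibitor of metalloproteinases chosen after its value was seen, rose 11.7-fold (log2 3.54, SE 0.20). The median was 0.96 (1.01 on design 026655 and 0.87 on 028005), with a camera adjusted p = 0.00545 and an adjusted p = 0.401 with an estimated correlation. Cytokines and chemokines rose for 18 of 35 members, with 5 lower and 12 not past the threshold (19 and 5 adjusted over the list alone). Csf2, which encodes GM-CSF, was measured on 2 of 3 skin arrays and rose (log2 6.80, SE 0.43), and Ccl2, a monocyte-attracting chemokine chosen after its value was seen, rose 4.58-fold. The lymphoid-tissue chemokine Ccl19 was 94.6-fold lower (log2 -6.56, SE 0.27). The other members that fell, named after their values were seen, were Ccl11, Cxcl13 (at least 6.55-fold lower), Cxcl14 and Il15. The list's median was 0.72 (0.95 and 0.55 on designs 026655 and 028005), with a camera adjusted p = 0.00358 and an adjusted p = 0.401 with an estimated correlation. Growth factors went both ways, with 21 of 46 higher, 12 lower and 13 not past the threshold (21 and 13 adjusted over the list alone). Ereg, a ligand of the EGF receptor, rose 91.2-fold and Pdgfa, a platelet-derived growth factor chain, 15.3-fold. The list was not called by camera (median 0.51, 0.61 on design 026655 and 0.26 on 028005, adjusted p = 0.0652). It was called higher with no array design term (adjusted p = 0.000831), with the 75th percentile over detected probes (0.0338), under normexp (0.0230), with detection on all 6 arrays (0.0478), in the authors' deposited table (0.0277) and without skin replicate 1 (0.0377), and not with an estimated correlation (adjusted p = 0.344). Fry, which tests a list against no change and not against other genes, gave an adjusted p = 0.000708.

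Cell cycle genes rose for 32 of 43 members, with 0 lower and 11 not past the threshold (34 and 0 adjusted over the list alone). The mitotic kinase Cdk1 rose 5.82-fold (log2 2.54, SE 0.20, and 1.41 with the mean of all probes), the ubiquitin-conjugating enzyme Ube2c rose 4.85-fold, and Kif2c, a mitotic kinesin measured on 1 of 3 skin arrays, had a log2 difference of 2.00. The proliferation marker Mki67, chosen after its value was seen, rose 3.07-fold and lost its call with no array design term (adjusted p = 0.0822). The median was 1.36 (1.35 on design 026655 and 1.30 on 028005), with a camera adjusted p = 5.04e-11 and an adjusted p = 0.344 with an estimated correlation. Genes of the endoplasmic reticulum and its stress response rose for 20 of 37 members, with 16 not past the threshold and 1 lower, Herpud1, named after its value was seen (20 and 1 adjusted over the list alone). The disulfide isomerases Pdia5 and Pdia4 rose by a log2 of 1.67 and 1.25, and lost their calls with no array design term (adjusted p = 0.0661 and 0.273). The median was 0.56 (0.60 and 0.60 on the designs 026655 and 028005), with a camera adjusted p = 0.000282 and an adjusted p = 0.344 with an estimated correlation. Glycolysis and hypoxia genes rose for 16 of 33 members, with 4 lower and 13 not past the threshold (17 and 4 adjusted over the list alone). The carbonic anhydrase Car12 rose 11.9-fold and the lactate transporter Slc16a3 3.84-fold. The 4 that fell were Adm, which encodes adrenomedullin (log2 -2.48, SE 0.22), and Aldoc, Egln3 and Pfkfb4, named after their values were seen. The median was 0.56 (0.53 on design 026655 and 0.45 on 028005), with a camera adjusted p = 0.0210, an adjusted p = 0.344 with an estimated correlation, and no call on design 026655 alone (adjusted p = 0.0629) or with no array design term (adjusted p = 0.151).

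Markers of quiescent dermal fibroblasts fell for 15 of 27 members and rose for 7, with 5 not past the threshold (17 and 7 adjusted over the list alone). Of these 27 genes 12 are also in other lists. Pi16, a marker of adventitial fibroblasts, was 19.2-fold lower (log2 -4.27, SE 0.18), and Smpd3, measured on 1 of 3 wound arrays, also fell (log2 -3.75, SE 0.62), whereas Dlk1 of the same list rose. Gsn, Cd34 and Pdgfra, chosen after their values were seen, fell by 2.05, 1.61 and 1.30 on the log2 scale, Cd34 and Pdgfra losing their calls with no array design term (adjusted p = 0.0846 and 0.235). The median was -1.30 (-1.34 on design 026655 and -1.50 on 028005), with a camera adjusted p = 0.00313 and an adjusted p = 0.401 with an estimated correlation. Dermal genes of the hair follicle fell for 21 of 29 members, with 7 not past the threshold and 1 higher, Inhba, named after its value was seen (23 lower and 2 higher adjusted over the list alone). Of these 29 genes 18 are also in other lists. Bmp4 and Wif1, an inhibitor of Wnt ligands (62.3-fold lower, log2 -5.96, SE 0.68), led the decreases, with the transcription factor Sox18, measured on 2 of 3 wound arrays (log2 -5.29, SE 0.51). The list's median was -2.06 (-2.43 and -1.59 on designs 026655 and 028005), with a camera adjusted p = 1.48e-09 and an adjusted p = 0.344 with an estimated correlation. The wider Wnt pathway fell for 16 of 44 members and rose for 8, with 20 not past the threshold (18 and 8 adjusted over the list alone). Of the list's genes 11 are also in other lists. The inhibitor Wif1, named above, is one of them and had the largest decrease of the Wnt list. Rspo1, which enhances Wnt signals, fell 53.3-fold and Lef1, a transcription factor of the pathway, 26.6-fold. The list holds both enhancers and inhibitors of Wnt signals, so its decrease does not give the direction of signalling. Its median was -0.38 (-0.42 on design 026655 and -0.33 on 028005), with a camera adjusted p = 0.00961 and an adjusted p = 0.344 with an estimated correlation. Keratinocyte markers were lower in the same arrays, with a median of -2.78.

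The sort took cells negative for CD45, a marker of white blood cells, and CD31, a marker of endothelial cells. Ptprc, which encodes CD45, did not differ past the threshold (log2 -0.21, SE 0.16, adjusted p = 0.367, and 0.01 with normexp background correction) and was well above background on 3 of 3 skin arrays and 1 of 3 wound arrays. Pecam1, which encodes CD31, was well above background on all 6 arrays and did not pass the threshold (log2 0.37, SE 0.17, adjusted p = 0.153). Keratinocyte markers were lower in wound cells for 26 of 31 members, with 4 not past the threshold and 1 higher, Itga6, named after its value was seen (26 and 1 adjusted over the list alone). Krt1, a keratin of the differentiated epidermis, was at least 22.8-fold lower (adjusted p = 0.00283), and Krtdap and the desmosomal protein Dsp, each measured on 1 of 3 wound arrays, had log2 differences of -6.36 and -6.31. The bound of Krt1 is for the mean over arrays. In the pair on design 028005 its log2 difference as read was -3.90, which is less than the bound. The basal keratins Krt5 and Krt14, chosen after their values were seen, were 20.1-fold and 4.75-fold lower. The median was -2.78 (-3.15 on design 026655 and -2.30 on 028005), with a camera adjusted p = 5.04e-11 and an adjusted p = 0.344 with an estimated correlation. Only 13 of 26 entries for the hair shaft and root sheath were tested. Hair shaft and root sheath genes fell for 5 of these 13 members, with 8 not past the threshold (0 higher and 7 lower adjusted over the list alone). They were the keratins Krt71 and Krt25 (at least 27.3-fold and at least 12.7-fold lower) and Krt28, measured on 1 of 3 wound arrays, with Krtap11-1 and Tchh, named after their values were seen. The median was -0.59 (-0.60 and -1.31 on designs 026655 and 028005), the camera adjusted p = 0.0133, and the adjusted p = 0.401 with an estimated correlation. With genes detected on all 6 arrays the hair shaft list was not called (adjusted p = 0.258).

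Schwann cell and neural markers fell for 15 of 27 members, were called higher for 2 and did not pass the threshold for 10 (16 and 2 adjusted over the list alone). Gldn led the decreases, Mal was at least 4.96-fold lower, and the myelin gene Mbp, chosen after its value was seen, fell by 2.83 on the log2 scale. The 2 called higher were Fabp7 (at least 7.48-fold higher, adjusted p = 0.000132) and Ncam1, named after its value was seen (log2 0.57, adjusted p = 0.0454). For Ncam1 the probes differ, with 1 of 3 detected probes called lower and 0 called higher when probes were tested singly, and a log2 of 0.08 with the mean of all probes and 0.02 in the authors' deposited table. The median was -0.85 (-0.99 on design 026655 and -1.27 on 028005), with a camera adjusted p = 0.000145 and an adjusted p = 0.344 with an estimated correlation. CD45 marks white blood cells, so the gates need not remove red cells, and their share in each sort was not tested. Only 8 of 15 erythroid entries were tested. Erythroid genes fell for 6 of these 8 members, with 0 higher and 2 not past the threshold (6 and 0 adjusted over the list alone). The beta globins Hbb-bt, Hbb-b1 and Hbb-b2 were measured on 2 of 3 wound arrays and had log2 differences of -3.80, -3.36 and -3.07. Without wound replicate 1 they were -4.81, -4.26 and -3.75, and Hbb-bt was -2.93 without wound replicate 2. On design 026655 alone Hbb-bt and Hbb-b1 lost their calls (adjusted p = 0.0559 and 0.0758), as did Hbb-b1 without skin replicate 1 (0.0599), without wound replicate 2 (0.0632) and with no filter (0.05003). The median was -2.37, with -1.52 on design 026655 and -4.04 on 028005 (camera adjusted p = 0.00545, and adjusted p = 0.344 with an estimated correlation). Only 11 of 32 entries for lymphoid markers were tested. Lymphoid markers rose for 5 of these 11 members, with 0 lower and 6 not past the threshold (5 and 0 adjusted over the list alone). They were the adaptor Skap1 (at least 8.47-fold higher), the B cell receptor component Cd79b (log2 3.61, SE 0.17), the kinase Lck (log2 1.21), which lost its call with no array design term (adjusted p = 0.310), and Cd4 and Ebf1, named after their values were seen. The median was 0.50 (0.51 and 0.70 on designs 026655 and 028005), with a camera adjusted p = 0.0242, an adjusted p = 0.344 with an estimated correlation, and no call in the authors' deposited table (adjusted p = 0.122), with no filter (0.0890), with the mean of all probes (0.0544) or with detection on all 6 arrays (0.0613). Endothelial markers went both ways, with 8 of 30 higher, 7 lower and 15 not past the threshold (9 and 7 adjusted over the list alone). Sox18, named above with the hair follicle genes and measured on 2 of 3 wound arrays, is also in this list and had its largest decrease (log2 -5.29). The chemokine receptor Ackr1 was 33.0-fold lower and Cd93 22.4-fold higher. That list was not called (median 0.15, 0.38 on design 026655 and -0.15 on 028005, camera adjusted p = 0.657).

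**Figure D3:**
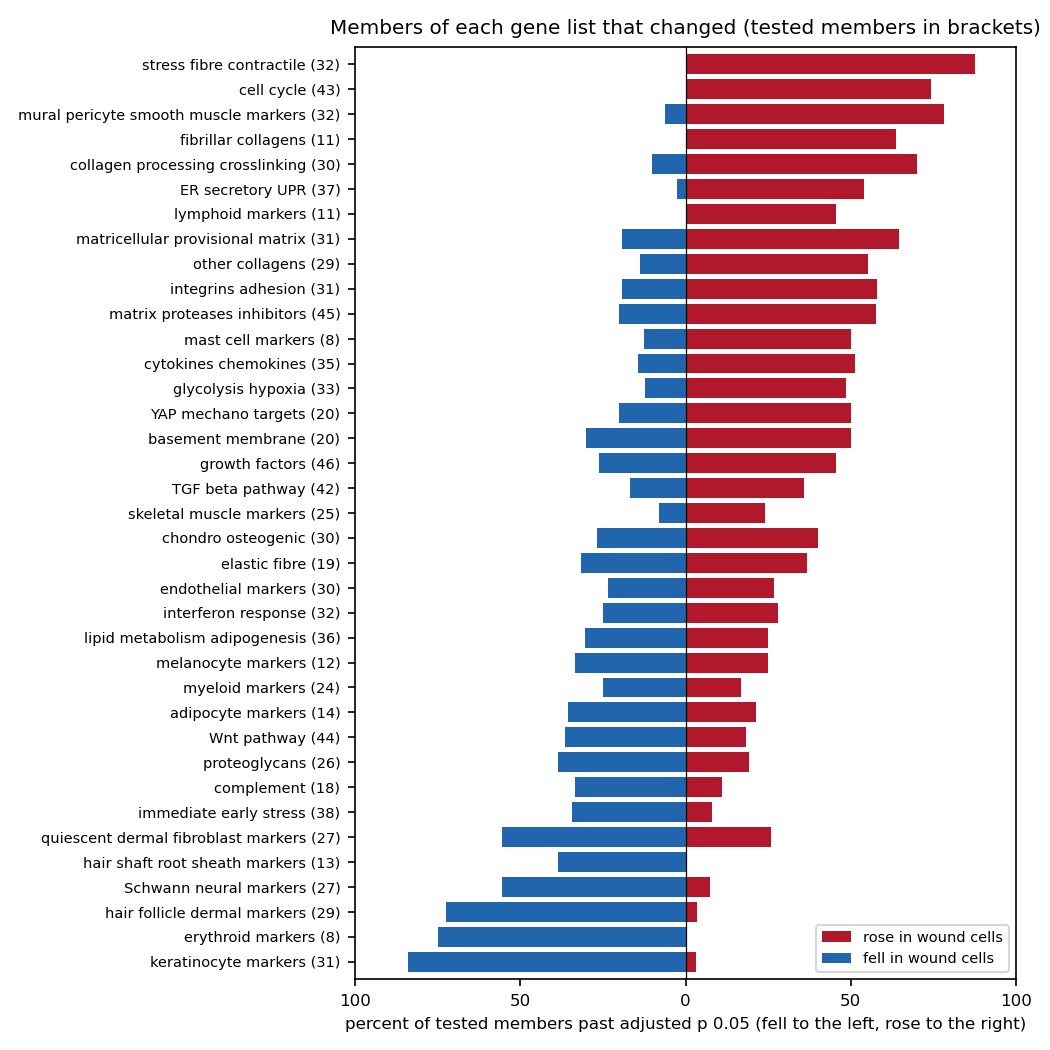
Percent of the measured members of each of 37 gene lists that rose (right) or fell (left) in wound cells at an adjusted p under 0.05. Stress fibre genes rose for 28 of 32 members and keratinocyte markers fell for 26 of 31.

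Of the 37 lists, camera called 20 at its preset correlation (12 higher and 8 lower in wound cells) and 0 with an estimated correlation. The latter test rests on 3 residual degrees of freedom, so calls were hardly possible. Glycolysis and hypoxia genes and lymphoid markers had estimated correlations of -0.00068 and -0.077, under the preset 0.01. They lost their calls all the same (camera adjusted p = 0.344 each), so the losses of these lists do not come from correlated genes. The other called lists had estimated correlations above the preset, from 0.032 for matricellular genes to 0.393 for fibrillar collagens. For them the preset assumes less correlation than was estimated, which may add to their losses, and the part of each was not tested. Splits of the 6 arrays that mixed both groups, with 3 arrays on each side, gave up to 16 called lists at the preset correlation and 0 called genes. Such splits keep part of the wound against skin difference and put the rest into the residual spread. Neither count therefore stands for the absence of a difference. Of genes named after their values were seen, Cd4, Col17a1, Cxcl14, Itga6 and Ncam1 lost their calls on design 026655 alone (adjusted p = 0.153, 0.0524, 0.0724, 0.0768 and 0.143), Herpud1 without skin replicate 1 (adjusted p = 0.150), Col13a1 and Col17a1 under normexp (adjusted p = 0.0617 and 0.0739), and Pfkfb4 and Tll1 with the mean of all probes (adjusted p = 0.0545 and 0.147). With no array design term these and Aldoc, Ebf1, Egln3, Il15 and Ndufa4l2 were not called, each differing by less than 1.74. Of 18 alternatives, 3 of them the same fit, Cd4 and Ncam1 passed the threshold in 6, Itga6 in 7, Herpud1 in 11 and Cxcl14 and Tll1 in 13.

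The size of other named differences also moved by more than 1.5-fold. With the mean of all probes the log2 difference was 3.64 for Tnc, 3.097 for Col12a1, -5.84 for Ccl19, -3.86 for Dsp, -3.67 for Krt28, -3.73 for Krt5, -1.79 for Mbp, -1.02 for Col4a4 (-1.15 with the brightest shared probe) and -1.74 for Krtap11-1. Normexp drew matrix, contractile and signalling genes nearer to 0, with 4.34 for Tes, 3.93 for Col8a1, 2.40 for Col6a5, 3.17 for Tnc, 2.91 for Myh11, 1.57 for Kcnmb1, 2.19 for Casq2, 4.83 for Csf2, 5.17 for Ereg, 2.64 for Car12, 0.62 for Kif2c, -3.36 for Smoc1, -0.43 for Col13a1, -0.42 for Col17a1, -1.09 for Col4a4, -5.95 for Ccl19, -1.35 for Cxcl13, -0.85 for Il15, -1.01 for Egln3, -1.21 for Smpd3, -3.54 for Sox18 and -3.76 for Lef1. Among markers of other cell types it gave -2.75 for Krt1, -3.30 for Krtdap, -3.49 for Dsp, -3.37 for Krt5, -1.51 for Krt14, -2.83 for Krt71, -2.03 for Krt25, -2.31 for Krt28, -2.38 for Krtap11-1, -1.50 for Tchh, 0.97 for Fabp7, -1.11 for Mal, -2.05 for Mbp, 1.33 for Skap1, 2.21 for Cd79b, 3.19 for Cd93, and -2.71, -1.58 and -1.83 for Hbb-bt, Hbb-b1 and Hbb-b2. On design 026655 alone the values were -6.56 for Smoc1, -7.08 for Wif1, 4.19 for Car12, -2.94 for Smpd3, -5.95 for Sox18, -7.47 for Krtdap, -7.46 for Dsp and -2.75 for Hbb-b1. Without skin replicate 2 they were 2.89 for Car12, -5.50 for Krtdap, -5.45 for Dsp and -3.98 for Hbb-b1, without wound replicate 1 -4.40 for Smpd3, and without wound replicate 2 -5.38 for Krtdap. For genes written with a bound, fits on signals as read also moved. On design 026655 alone Krt1 went from -6.33 to -7.55, Krt71 from -5.70 to -4.89, Krt25 from -5.20 to -4.36 and Calm4 from -7.51 to -8.84. Without skin replicate 2 Krt1, Krt25 and Calm4 stood at -5.36, -5.81 and -6.53. Without wound replicate 1 Krt1 and Calm4 stood at -5.71 and -6.87.

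The array designs gave similar differences across genes. The log2 difference on design 028005 correlated with that on design 026655 at a Pearson r of 0.845 and a Spearman rho of 0.732, both across genes, which are not independent replicates, so no p is given. The 2 arrays per group of design 026655 alone called 4496 genes, and 4319 of these (96.1%) had the same sign on design 028005. That design holds 1 array per group and gives no test of its own. All 39429 probes of design 026655 are also on design 028005, but 30 gene names came only from the accessions of design 028005 and 4 only from those of design 026655. Of 32 probes with such a name of design 028005 and a value on both of its arrays, 31 are also on design 026655, where they have another name or none. For these names the values come from 1 array per group, and those of the same probes on design 026655 were not set beside them. On the arrays of design 028005 the probe named Fer1l5 was detected in wound cells only (at least 4.88-fold higher), and those named Mup1, a major urinary protein, and Cfap57 in skin cells only (at least 8.25-fold and at least 1.96-fold lower in wound cells). The probe named Btbd35f13 was also detected in skin cells only, and its bound (0.784-fold) shows no decrease. Of the 4 names of design 026655, Tc2n had a log2 difference of -3.18 on that design (SE 0.56, adjusted p = 0.0445, detected on 3 of 4 arrays) and Rn28s1 did not pass the threshold there (log2 0.32, adjusted p = 0.581). These names were chosen after their values were seen.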

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

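The tests on keratinocyte markers, mural cell markers and the main collagen chains were chosen only after those results were seen, and the splits of the arrays were planned before. The genes named with those patterns were chosen after their values were seen, except Acta2.

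Probes for transcribed intervals of the genome, on design 028005 only and with no gene name, gave signal outside the comparisons of genes. Of 16194 such probes 10597 were well above background on the skin or the wound array. Of these, 304 (2.87%) were 8-fold or more higher on the wound array and 126 (1.19%) 8-fold or more lower, comparing 1 array with 1, which allows no test. These counts take the signal of undetected probes as read. With bounds in its place they are 114 and 46, and among the 7201 probes detected on both arrays 32 and 31. The median processed signal of the negative controls was 4.98 on the wound array and 2.59 on the skin array. Spots with an outlier mark numbered 678 on the wound array and 249 on the skin array, over all of its probes. The skin array alone detected 2779 of the interval probes and the wound array alone 617. The largest increases by signal as read, in coordinates of build mm9, were at chromosome 8 from 73645975 to 73696275 (at least 52.2-fold), chromosome 12 from 76776232 to 76776905 (at least 40.7-fold) and chromosome 2 from 94046243 to 94070067 (at least 31.8-fold). These probes were not detected on the skin array, so their rank is not a measured order. The largest decreases among intervals detected on both arrays were at chromosome 4 from 33375464 to 33377138 (133-fold) and chromosome 18 from 90750100 to 90772025 (73.0-fold). No gene was looked up at these positions. Among 4061 probes on both designs with neither a symbol nor a gene identifier, 359 were called higher and 286 lower in wound cells by the limma model.

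The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 5676 genes and the highest other split 0, so that 1 of the 10 gave as many. For gene lists at the preset correlation the real split called 20 and the highest other 16, and again 1 of the 10 gave as many. Each of the other 9 splits mixed both groups and called lists although it called 0 genes. A mixed split keeps part of the difference between wound and skin cells, so its list calls are no rate of false calls. The rest of that difference widens the residual spread, so 0 called genes could be foreseen and does not speak against chance.

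Keratinocyte markers fell in wound cells (median -2.78 on the log2 scale). Of the list's 39 genes on the arrays 31 (79.5%) were well above background on all skin arrays and 15 (38.5%) on all wound arrays. All 26 members that fell are among the 31, so this restates the decrease and decides nothing about keratinocytes or their RNA in the skin sort, which stay open. The CD45 and CD31 gates do not remove epithelial cells. The skin cells were also gated on a low reporter signal, which would leave out cells without the reporter, and how far it did was not tested. Of the genes 3 are also in other lists. The abundant keratins Krt10, Krt5 and Krt14 stood at log2 levels of 3.29, 1.65 and -1.09 against the 75th percentile of the skin arrays and at -0.69, -2.68 and -3.34 in wound cells. The difference of Krt10, -3.99, was -4.91 on design 026655 alone, -4.89 with the mean of all probes and -3.23 without skin replicate 2. The 3 scalings tried gave medians of -2.78, -2.75 and -2.85, so the choice among them does not account for the decrease. They moved the list by little, so they do not test array scaling more widely. A difference between dermis and wound tissue in what the sort collected stays open and was not tested.

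Mural cell markers rose in wound cells (median 2.98), and 8 of their genes are also in other lists. A larger share of mural cells in the high-reporter gate may contribute, and the CD45 and CD31 gates do not remove them. Of 22 members with a low level in skin cells 21 rose, while 4 of 10 with a high level did, and both that source and a change within the wound cells allow this, so they cannot be told apart here. The members were split by the skin level, which also enters the difference, so this contrast is partly built in. Some low members, such as Kcnmb1 and Casq2, entered the test through detection on the wound arrays only. The abundant markers Acta2, Tagln and Rgs5 stood at 2.27, 3.31 and 0.47 in skin cells and 6.98, 6.52 and 5.25 in wound cells. The 3 scalings tried gave medians of 2.98, 2.96 and 2.91, so the choice among them does not account for the increase. They moved this list by little too, so array scaling was not tested more widely.

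Col1a1, Col1a2, Col3a1 and Sparc lay near no difference, with log2 values from 0.02 for Sparc to 0.09 for Col1a1, and under the 75th percentile over detected probes Col1a2, Col3a1 and Sparc turned slightly negative (-0.05, -0.00 and -0.05). Of the 163 genes at least as bright as Col1a1, the dimmest of these, 9 differed 2-fold or more with a call. This argues against compression of bright spots as the whole cause for Col1a1. It does not settle the matter for Col3a1, Sparc and Col1a2, which stood at 7.91, 8.72 and 9.06 in skin cells against 6.84 for Col1a1. The brightness of the 9 genes was not compared with theirs. These 9 are 5.52% of the bright genes, against 20.2% of all tested genes, so partial compression could still contribute. No biological explanation was tested.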

How the results depend on the processing

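No alternative here was added after the data were seen, and the replicates to leave out were planned. Of 194 named genes 186 were called, 186 kept their direction in every alternative and 141 also stayed past the threshold, the most calls being lost with no array design term. Calls fell to 1742 with no array design term (841 higher, 901 lower). That model gave every gene the same SE of 0.62, so its calls are the genes that differ by a log2 of 1.74 or more, and each call lost there is a smaller difference. Calls fell to 3179 at an adjusted p under 0.01 (1694 and 1485), a stricter threshold by construction. Normexp background correction gave 2159 calls of 2-fold or more (1103 and 1056). Without 1 array, calls lay between 3740 and 4991 and higher calls between 2010 and 2574, with fewer samples. Camera with an estimated correlation, which rests on 3 residual degrees of freedom, called 0 lists, 0 higher and 0 lower. Of probes with a name from design 028005 only, 8 differed 2-fold or more with no filter against 4, by signals as read and not as bounds, since the filter drops probes that neither array detected. The fitted log2 difference moved by more than 1.5-fold for 93 named genes in some alternative, for 82 under normexp (all 82 nearer to 0, with an offset of 50 added by construction), 25 on design 026655 alone, 22 with the mean of all probes, 22 in the authors' deposited table and 2 with the brightest shared probe. Without skin replicates 1 and 2 it moved for 1 and 9, and without wound replicates 1 and 2 for 7 and 3. Leaving out either replicate 3 is the same fit as design 026655 alone. The cause was not tested. The normexp alternative changed the signal used, the background correction and the offset at once, so the part of each is not known. With the pair of arrays as a block 5577 genes were called, 5287 of them among the 5676. The labels do not say that the numbers pair the arrays, and the deviations of same-numbered arrays on design 026655 correlated at 0.153. Of the 5676 calls, 5294 were kept under quantile normalization, 5292 with the 75th percentile over detected probes, 5035 under normexp, 4194 on design 026655 alone and 4778 of 5551 in the authors' deposited table.

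Values that were not called changed sign, and the cause was not tested. Before these changes they were 0.02 for Col1a2 and Sparc, 0.07 for Col3a1 and -0.21 for Ptprc. With the 75th percentile over detected probes Col1a2 was -0.047, Col3a1 -0.0036 and Sparc -0.054, and the authors' deposited table gave -0.035 for Col1a2. Without 1 array Col1a2 ranged from -0.097 to 0.12, Col3a1 from -0.054 to 0.18 and Sparc from -0.085 to 0.098. Ptprc was 0.01 under normexp. Of the gene lists, as the mean shift of members against other genes in units of z (for fry, the mean moderated t), elastic fibre genes turned from -0.064 to 0.013 with no array design term, 0.086 on design 026655 alone, 0.0068 with the 75th percentile over detected probes, 0.032 with the mean of all probes and 0.100 in the authors' deposited table, and ranged from -0.27 to 0.086 without 1 array. Myeloid markers turned from -0.029 to 0.58 with no array design term, 0.42 on design 026655 alone, 0.090 under quantile normalization, 0.023 with the 75th percentile over detected probes, 0.11 with the mean of all probes, 0.12 with no filter and 0.49 by fry, and ranged from -0.27 to 0.42. Chondrogenic and osteogenic genes turned from 0.015 to -0.29 with no array design term, -0.037 on design 026655 alone, -0.30 under normexp, -0.015 with detection on all 6 arrays and -0.29 by fry, and ranged from -0.037 to 0.039. Interferon genes stood at 0.14 and ranged from -0.21 to 0.34 without 1 array. Basement membrane genes turned from 0.43 to -0.12 with no array design term, mast cell markers from 1.04 to -0.033 with no filter and adipocyte markers from -0.47 to 0.0075 by fry. Lists that were not called gained a call in 29 values, 9 of them by fry, which tests against no change and not against other genes, among these proteoglycans (adjusted p = 0.0317), the TGF-beta and BMP pathway (0.000156), lipid metabolism (0.0278), melanocyte markers (0.0209) and skeletal muscle genes (0.0174), while the estimated correlation called none of them. Signal over background limits the genes written with a bound, 121 called higher with no skin array and 189 called lower with no wound array well above background.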

Other observations

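No test in this part was chosen after its result was seen, and members of a list that are named outside the fixed rule were chosen afterwards. Adhesion genes rose for 18 of 31 members, fell for 6 and did not pass the threshold for 7 (18 and 7 adjusted over the list alone), without a call by camera (median 0.65, adjusted p = 0.0533). The list was called higher with the 75th percentile over detected probes (adjusted p = 0.0338), under normexp (0.0294), with detection on all 6 arrays (0.0478), in the authors' deposited table (0.0435), without skin replicate 1 (0.0377) and without wound replicate 1 (0.0306), and not with an estimated correlation (adjusted p = 0.552). Fry, which tests a list against no change and not against other genes, gave an adjusted p = 0.0265. N-cadherin (Cdh2) rose (log2 4.32, SE 0.33) and the collagen-binding integrin Itga1 9.82-fold by its brightest probe (log2 1.43 with the mean of all probes and 1.37 in the authors' deposited table, with 1 of 2 detected probes called), while R-cadherin (Cdh4) fell (log2 -5.84, SE 0.24). Targets of mechanical YAP signalling rose for 10 of 20 and fell for 4 (10 and 5 adjusted over the list alone, median 0.44, camera adjusted p = 0.0885), and were called higher in the authors' deposited table (adjusted p = 0.0435) and without skin replicate 2 (0.0496), and not with an estimated correlation (adjusted p = 0.401), with an adjusted p = 0.00526 by fry against no change. Fjx1 rose (log2 3.11), Foxf2 was at least 4.73-fold higher, and Nt5e fell (log2 -2.75) with Ccn1, Gadd45b and Nuak2. In the TGF-beta and BMP pathway 15 of 42 members rose and 7 fell (15 and 8 adjusted over the list alone, median 0.21, camera adjusted p = 0.236). Bmp4 fell, Bmper, which binds BMPs, rose (log2 3.36), and the receptor Bmpr1b, measured on 1 of 3 skin arrays, rose (log2 6.03). Elastic fibre genes rose for 7 of 19 and fell for 6 (8 and 6 adjusted over the list alone), with fibrillin 2 (Fbn2) higher (log2 3.53) and Efemp1 and Ltbp4 lower (log2 -3.31 and -2.27). Their median was -0.00, their mean 0.02 and the direction of camera lower (adjusted p = 0.962). Proteoglycans fell for 10 of 26 and rose for 5, which were Gpc1 (log2 3.24), Prg4 (log2 2.61), Aspn, Gpc6 and Sdc1 (12 lower and 5 higher adjusted over the list alone, median -0.40, camera adjusted p = 0.0892), with Fmod, which binds collagen fibrils, lower (log2 -2.47). Basement membrane genes rose for 10 of 20 and fell for 6 (10 and 7 adjusted over the list alone), with Nid2 higher (log2 2.38) and Lamc3 and Frem1 lower (log2 -4.87 and -2.39). Their median was 0.39 and their mean -0.06, and the direction of camera was higher (adjusted p = 0.539).

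Interferon-response genes rose for 9 of 32 and fell for 8 (11 and 9 adjusted over the list alone, median 0.23, with 0.45 on design 026655 and -0.08 on 028005, camera adjusted p = 0.831). Oas1a, Ifi44 and Oasl1 led the increases (log2 4.01, 2.65 and 2.29). Complement genes fell for 6 of 18 and rose for 2, among them Cfi, measured on 1 of 3 skin arrays (7 and 2 adjusted over the list alone, median -0.44, camera adjusted p = 0.0696), and C3 fell (log2 -2.35) as did Masp1 (log2 -2.40). The complement list was called lower under normexp (adjusted p = 0.0402), with the mean of all probes (0.0201), with detection on all 6 arrays (0.0250), in the authors' deposited table (0.0334) and without skin replicate 2 (0.00631), and not with an estimated correlation (adjusted p = 0.637). Chondrogenic and osteogenic genes rose for 12 of 30 and fell for 8 (12 and 10 adjusted over the list alone), with Runx3, measured on 2 of 3 wound arrays, and Alpl lower (log2 -4.87 and -2.97) and Sost at least 2.77-fold lower. Their median was 0.19, their mean -0.16, the direction of camera higher (adjusted p = 0.974) and that of fry lower. Genes of lipid metabolism fell for 11 of 36 and rose for 9 (12 and 11 adjusted over the list alone, median -0.22, camera adjusted p = 0.274), Apoe falling (log2 -3.86) and Ebf2 rising (log2 2.52). Immediate early and stress genes fell for 13 of 38 and rose for 3, Gadd45a, Klf6 and Rhob (13 and 5 adjusted over the list alone). Socs3, Fos and Cebpd fell (log2 -1.95, -1.90 and -1.81). The median was -0.23 (-0.28 on design 026655 and -0.04 on 028005), with a camera adjusted p = 0.0127, an adjusted p = 0.552 with an estimated correlation, and no call with no array design term (adjusted p = 0.0833). Klf6, Rhob and Gadd45b lost their calls on design 026655 alone (adjusted p = 0.158, 0.0903 and 0.0779), and Nuak2 without skin replicate 1 (adjusted p = 0.160). With no array design term Aspn, Ccn1, Gadd45a and Gpc6 were not called, that model calling only log2 differences of 1.74 or more.

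Markers of other cell types whose lists camera did not call at its preset correlation had members that rose and members that fell. Not all entries were tested, with 24 of 39 for myeloid, 8 of 19 for mast cell and 12 of 17 for melanocyte markers. For skeletal muscle genes 25 of 38 entries were tested and for adipocyte markers 14 of 24. Myeloid markers rose for 4 of 24 and fell for 6 (4 and 7 adjusted over the list alone). The risers were Itgax (log2 5.62) and S100a9 (log2 3.37), each measured on 1 of 3 skin arrays, Ms4a7, measured on 2 of 3 skin arrays, and Ctss, the median was 0.18 and the mean 0.37, and the direction of camera was lower (adjusted p = 0.974). Mast cell markers rose for 4 of 8, Il1rl1, the receptor of interleukin 33 (79.9-fold, log2 6.32, SE 0.15), Gata2 and Kit, each measured on 1 of 3 skin arrays, and Rab27b, while Mcpt4, a mast cell protease, was at least 2.93-fold lower (4 and 1 adjusted over the list alone, median 0.81, camera adjusted p = 0.281), and the list was called higher with no array design term (adjusted p = 0.0165) and not with an estimated correlation (adjusted p = 0.632), with an adjusted p = 0.00519 by fry against no change. Melanocyte markers rose for 3 of 12, Ednrb (log2 2.07), Kit and Slc24a5, and fell for 4, Mlana and Gpnmb (log2 -3.06 and -3.03), Mitf and Sox10 (3 and 4 adjusted over the list alone, median -0.11, camera adjusted p = 0.553). Skeletal muscle genes rose for 6 of 25, led by Acta1 and Des (log2 3.68 and 3.36), and fell for 2, Pax7 (at least 3.32-fold lower) and Pvalb (6 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.287). Adipocyte markers rose for 3 of 14, Ucp1 (at least 9.90-fold higher), Fabp4 (log2 2.76) and Sncg, and fell for 5, Plin4 (log2 -4.68), Adrb3, measured on 2 of 3 wound arrays, Cidea, G0s2 and Gpd1 (3 and 5 adjusted over the list alone, median -0.30, camera adjusted p = 0.553, and fry in the other direction). Gpd1, Rab27b and Sox10 lost their calls on design 026655 alone (adjusted p = 0.138, 0.0535 and 0.0597), Cidea, Ctss and Kit without skin replicate 1 (adjusted p = 0.0903, 0.0836 and 0.115), and Ms4a7 without wound replicates 1 and 2 (adjusted p = 0.0574 and 0.0633). Of 18 alternatives Klf6 passed the threshold in 5, and Cidea, Gpd1, Nuak2 and Rhob in 10 each, and Kit in 9 of 17. With no array design term G0s2, Mitf and Slc24a5 were not called.

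The size of other differences named in this part moved by more than 1.5-fold. With the mean of all probes the log2 difference was 1.78 for Prg4, -3.35 for Runx3, -1.53 for Adrb3 and -2.77 for Pvalb. The authors' deposited table gave 5.30 for Bmpr1b. Normexp gave -4.91 for Cdh4, 0.70 for Foxf2, 2.77 for Bmpr1b, 1.52 for Ifi44, 1.67 for Cfi, -0.66 for Sost, -1.81 for Alpl, -3.10 for Runx3, 2.56 for Itgax, 0.97 for S100a9, 0.56 for Ms4a7, 0.73 for Gata2, 0.33 for Kit, which was not called there (adjusted p = 0.189), -0.53 for Mcpt4, -2.06 for Mlana, 0.68 for Slc24a5, 2.72 for Des, -0.60 for Pax7, 1.09 for Ucp1, -3.41 for Plin4 and -1.02 for Adrb3. On design 026655 alone the values were 6.69 for Bmpr1b, -3.03 for Masp1, -5.47 for Runx3, 4.13 for Gata2 and 1.92 for Kit. S100a9 was 4.07 without skin replicate 1 and Ms4a7 1.74 without skin replicate 2.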
